A study of Homo sapiens with 4 samples.

How the data were processed

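Total RNA from Reh cells, a human B-cell precursor leukemia line grown in RPMI medium, was measured 12 h after the addition of valproic acid, bortezomib, both drugs or neither, with 1 array in each of the 4 groups. The drug doses are not given in the sources used here. The RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays of 62976 spots, all on 1 slide with 1 scan time. Of these spots 58717 are not controls, for 42405 probes: 34085 spotted once, 7321 spotted 2 times and 999 spotted 10 times.

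The processed signal and its error are linear intensities that Feature Extraction corrected for background and for trends across the array and did not normalise between arrays, per the file headers. The headers name Feature Extraction 10.7.3.1 and probe positions on hg19, while Feature Extraction 9.1 and Partek are named per the submitters' processing notes. The value table deposited by the authors holds a ratio: each spot's processed signal divided by the median over the non-control spots of its array, as found by dividing the intensities anew (largest relative difference 2.1e-05, median of each array 1). It was therefore used as an alternative scaling only and gives the values of median centring.

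Values were the log2 of the processed signal minus the log2 of the array's 75th percentile over non-control spots. Spots of a probe were averaged, without those that the scanner software marked as outliers. A probe counted as measured when at least 50% of the spots kept were well above background, none was saturated and not all were outliers. Probes were named by a table of RefSeq accessions and symbols (GRCh38.p14), used for names only, and 26986 of the 42405 probes (63.6%) received a name, for 20310 genes. Each gene was represented by the probe with the highest mean log2 signal over the 4 arrays. Probes with no name, 8263 of them on loci of long intergenic non-coding RNAs, were left out of the comparisons. Near-identical paralogs, such as the metallothioneins or HSPA1A and HSPA1B, can hybridise to each other's probes.

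The choices of scaling, filter, gene lists, named genes, comparisons and first set of alternatives were made before the data were examined. With 1 array per group no p-value can be had for a comparison of 2 arrays, so genes were counted when the difference was at least 2-fold on arrays where they were measured. The error of a difference is the software's error of each spot carried through the averages and differences. It covers the spot and not the culture, the RNA or the labelling. The comparisons were each treatment against the control, the combination against each single drug, and the combination against the sum of the single-drug differences on the log2 scale. For a gene measured on 1 of the arrays compared, a bound was computed: the brighter signal against the higher of the lowest signal of a measured probe on the dim array (6.86 to 8.51 before scaling) and the dim probe's own signal. On each array this lowest probe had 2 spots, 1 of them well above background, and the lowest single spot well above background was at 14.1 to 15.9. Against that spot 47 of the 50 bounds would be lower, by up to 2.06 times.

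Named genes were the 12 highest and 12 lowest of each treatment against the control, the 6 highest and 6 lowest of each other comparison, and 5 in each direction by bound, by size of the difference. They had to carry a gene symbol, differ by more than 2 times the error and have no other measured probe that went the other way. Not every gene that the rule gives is printed, and differences that rested in part on spots not well above background were left out afterwards, apart from that of CCND2, given with this limit. From the lists, members with the greatest differences were named too, while members that went against their list, genes of the limma fit and genes in the plot of list members were chosen after their values were seen. The 26 gene lists cover pathways that either drug is known for, B-cell precursor genes and markers of other blood cells. Some genes are in more than 1 list, such as SLC7A11 (ATF4-CHOP and NRF2), SQSTM1 (NRF2 and autophagy), BBC3 and BAX (p53 and pro-apoptotic) and BCL2A1 (NF-kappaB and pro-survival). The median of a list was placed among 10000 random lists of as many measured genes, drawn from 20 bins of mean expression (at least 3 measured members), and called apart in the lowest or highest 2.5%. This describes the arrays and is not a test across cultures.

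Each drug's difference without and with the other drug was correlated across genes (Pearson's r and Spearman's rho, with no p-value since genes are not independent replicates). For the correlation of both drugs against the shared control, arrays with no effect were simulated 100 times with noise from replicate spots and from the non-additive part. An additive model of both drugs was fitted with limma 3.58.1 (R 4.3.3, eBayes, Benjamini-Hochberg threshold 0.05) to the 13912 genes measured on all 4 arrays, with 1 residual degree of freedom. Other computations used the data.table package 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

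The alternatives were median centring, quantile normalization, normexp background correction with an offset of 50, the authors' value table, the mean over probes, no filter on dim probes, genes above the median of mean signal, thresholds of 1.5-fold and 3-fold, a difference above 2 times its error, the mean over members, and a trended prior variance. Scaling on 8 spiked-in transcripts and leaving out bright patches were added after seeing the data. So was the definition of a patch: a spot was bright when its mean signal, after removal of the array median, was at least 2-fold above that on all 3 other arrays, and lay in a patch when at least 2 other bright spots were within 2 rows and 2 columns.

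The counting of genes was tested on simulated data with noise from the non-additive part: of 50 genes each at 1.5-fold, 2-fold, 3-fold and 4-fold it found 3, 25, 49 and 50, and 0 of 13712 unchanged genes. The noise was 0.154 per array, too small for an unchanged gene to reach 2-fold. The 0 therefore gives no rate of false calls for the real arrays, where the error of a difference reached 0.78 for a dim gene. The limma fit found 31, 50, 50 and 50 of the same sets and 10 of 13712 unchanged genes (0.0729%). In 200 simulated lists of 20 genes, 6% were called apart with no shift and 100% with a shift of 0.5. Depth is given as the share of spots well above background, and the number of arrays limits the precision.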

Results

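Gene expression was measured in Reh cells, a human line of B-cell precursor leukemia, after 12 h without drug, with valproic acid, with bortezomib, or with both drugs. Valproic acid inhibits histone deacetylases and bortezomib inhibits the proteasome. Each of the 4 groups was 1 sample on 1 array of a single slide, so no difference below has a replicate check, and the number of arrays limits the precision. Drug doses are not given in the sources used here. Of 58717 non-control spots, 65.3% were well above background on the control array, 68.4% with valproic acid, 65.3% with bortezomib and 67.0% with both drugs, and no spot was saturated. The 75th percentile of the processed signal was 1270, 1474, 1320 and 1385 in the same order. Differences are on the log2 scale, and the error after ± is the scanner software's spot error carried into the difference, with a median of 0.20 for the comparisons of 2 arrays. A list median is called apart when it lay in the lowest 2.5% or the highest 2.5% of 10000 random lists of the same size matched on mean expression, and percentiles refer to those lists.

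The valproic acid and control arrays were compared to ask which genes differed with the histone deacetylase inhibitor alone. Valproic acid went with more genes higher than lower: of 14185 measured genes, 893 were at least 2-fold higher and 180 at least 2-fold lower. CCND2, which codes for the cell cycle regulator cyclin D2, was higher by 4.41 ± 0.33 (21.2-fold). Its probe lies at positions 4414040 to 4414099 of chromosome 12 (hg19), and 1 of its 2 control spots was not well above background. The pro-apoptotic BCL2 relatives BMF and BIK were higher by 2.56 ± 0.20 and 2.23 ± 0.21. Genes of DNA replication, homologous recombination and mitosis were lower as groups, while p53 target genes were higher as a group.

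All 19 replication genes lay below the control, with a median of -0.51 (percentile 0.00), E2F1 at -0.81, RRM2 at -0.83 and MCM7 at -0.78, and none reached 2-fold. The 11 homologous recombination and checkpoint genes, all below the control, had a median of -0.43 (percentile 0.19), with RAD51AP1 at -0.72 and CHEK1 at -0.64. The 20 mitotic genes were all below the control as well, with a median of -0.37 (percentile 0.04). Of 15 measured p53 targets, 11 lay above the control with a median of 0.63 (percentile 100.0): the growth regulator TP53INP1 was higher by 1.74, SESN1 by 1.21 and the cell cycle inhibitor CDKN1A by 0.96. TP53I3 at -1.19 and MDM2, the ligase that targets p53 itself, at -0.84 went the other way. The genes of the integrated stress response (ATF4-CHOP) had a median of -0.59 (percentile 0.00), with 12 of 15 below the control, led by the transcription factor ATF5 at -1.95 ± 0.20 and the cystine transporter gene SLC7A11 at -0.95.

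The unfolded protein response genes had a median of 0.24 (percentile 99.96), with 13 of 16 above the control, DNAJB9 at 0.83 and none at 2-fold. All 7 measured metallothioneins were higher, with a median of 0.89 (percentile 100.0). These are near-identical paralogs whose transcripts can reach each other's probes, so they are not independent measures. The pro-apoptotic BCL2 family had a median of 0.30 (percentile 99.0), with HRK at 0.83 beside BMF and BIK, while BAX at -0.32 and BID at -0.28 lay below the control. The 5 pro-survival BCL2 genes lay below the control with a median of -0.24, which was not apart. Other lists not apart were the proteasome (-0.18), heat shock genes (-0.16), NRF2 targets (0.04), NF-kappaB targets (0.14), polyadenylated histone genes (-0.11), histone deacetylases (0.20), B-cell precursor genes (-0.25), autophagy genes (0.01) and cholesterol genes (0.00). Single members stood out of these medians: the autophagy gene WIPI1 at 3.65, the NF-kappaB target BIRC3 at 2.52 and the surrogate light chain gene IGLL1 at -1.18. B-cell precursor genes became apart and lower with quantile normalization (-0.17), the mean over probes (-0.27) and the mean over members (-0.27). With the mean over members, autophagy genes (0.46) and NF-kappaB targets (0.43) became apart and higher.

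Beyond the lists, the named genes measured on both arrays with the greatest differences included the non-coding RNAs FER1L4 and MIAT at 3.81 ± 0.21 and 3.78 ± 0.21. MTSS1 at 3.81 ± 0.29, MTURN at 3.69 ± 0.25, TMEM130 at 3.68 ± 0.31 and VWA5B2 at 3.66 ± 0.21 were near them. SLC25A41 at 4.69 ± 0.32 and LINC00994 at 4.45 ± 0.21 ranked above them, but the 1 spot of each lay in a patch of bright neighbouring spots on the valproic acid array. The lowest of the named genes measured on both arrays were LAMP5, a lysosome-associated membrane protein gene, on chromosome 20 (hg19 positions 9511041 to 9511100) at -3.10 ± 0.21, the dipeptidase gene DPEP1 at -2.31 ± 0.31, ATP4B at -2.26 ± 0.24, the dopamine receptor gene DRD5 at -2.08 ± 0.22 and the apoptosis inhibitor gene AVEN at -2.03 ± 0.20. ELFN2, PRR19, PVRIG, APOC1, AOX2P and GTF2IRD2 lay between -2.01 and -1.82. FBXO2 was not well above background in the control and at least 49.1-fold higher with valproic acid, TRIM7 at least 32.5-fold and PPM1J at least 32.1-fold. ARHGAP20 (at least 48.0-fold) and OR8U8 (at least 37.5-fold) lay in the same kind of patch. NEFH was not well above background with valproic acid and at least 8.94-fold lower, GPT2 at least 11.7-fold and EFEMP1 at least 6.85-fold, and MIR1-1HG and RGL3, at least 14.3-fold and 7.96-fold lower, had their control spots in bright patches.

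With normexp background correction 507 genes were higher and 114 lower. The share of higher genes among the 2-fold differences was 83.2%, and it was 66.2% with each array centred on its median and 91.0% with scaling on the spiked-in transcripts. The median of all genes was -0.05 here, -0.23 with median centring and 0.09 with spike-in scaling, so values with valproic acid are relative to that shift. The differences given as at least so many fold, here and below, would be up to 2.06 times lower against the lowest single spot well above background. No list median that was apart changed sign under any scaling or background setting. Among genes above the median of mean signal, the pro-apoptotic median was -0.18, and with the mean over probes it was 0.23, and neither was apart.

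**Figure D1:**
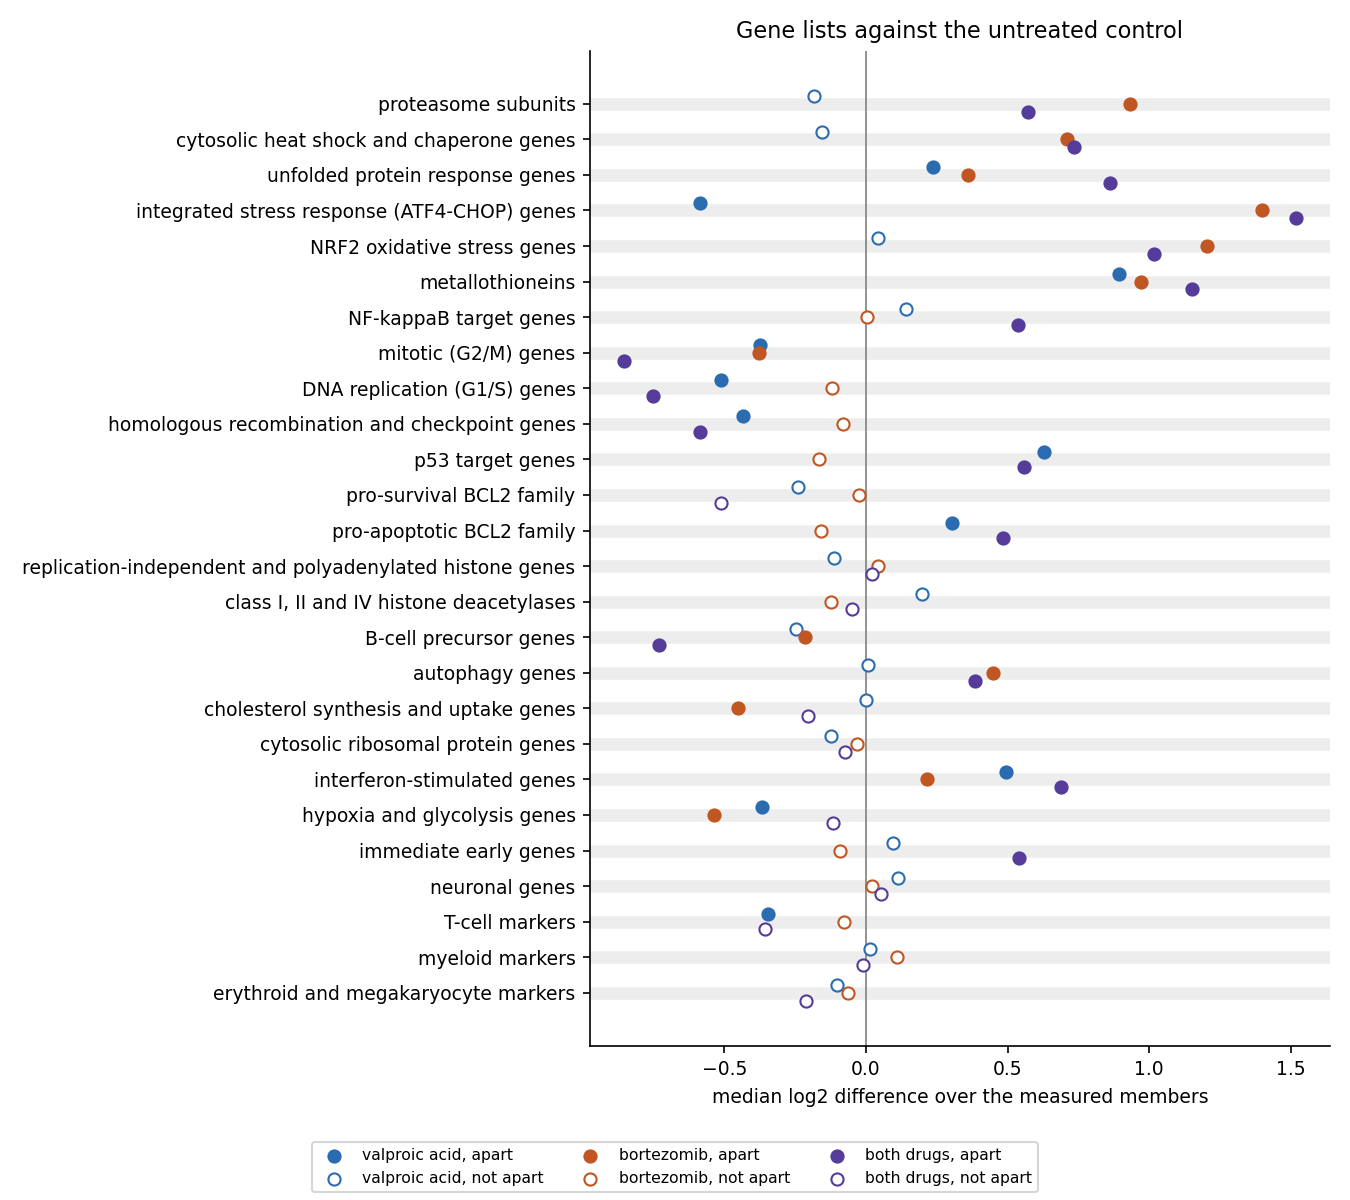
Points are medians over the measured members of each gene list of the log2 difference from the untreated control, for valproic acid (blue), bortezomib (orange) and both drugs (purple), from 1 array each, filled where apart from random lists matched on mean expression. The ATF4-CHOP list lies at -0.59 with valproic acid, 1.40 with bortezomib and 1.52 with both.

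The bortezomib and control arrays were compared to ask which genes differed with the proteasome inhibitor alone. Bortezomib went with higher expression of the proteasome's own subunit genes, cytosolic chaperones, ATF4-CHOP genes and NRF2 target genes. Of 14018 measured genes, 297 were at least 2-fold higher and 108 at least 2-fold lower. GABARAPL1, which codes for an autophagosome protein, was higher by 5.21 ± 0.21 (37.0-fold, and by 5.76 on its second probe; first probe at hg19 positions 10375579 to 10375637 of chromosome 12), the inducible chaperone gene HSPA1A by 2.59 ± 0.20, and the autophagy receptor gene SQSTM1 by 2.31 ± 0.20. Cholesterol genes, mitotic genes and B-cell precursor genes were lower as groups.

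Of the 35 proteasome genes, 34 lay above the control and 13 were at least 2-fold higher, with a median of 0.93 (percentile 100.0). The regulatory particle genes PSMD11, PSMD14 and PSMC2 were higher by 1.61, 1.51 and 1.47, while PSMA6 at -0.05 and PSMD5 at 0.02 were near the control. All 19 measured heat shock and chaperone genes lay above the control, with a median of 0.71 (percentile 100.0), and 5 were at least 2-fold higher, among them HSPA1B at 1.91, a near copy of HSPA1A, and HSPH1 at 1.23. BAG3, a co-chaperone gene, was not well above background in the control. The ATF4-CHOP genes had the highest list median, 1.40 (percentile 100.0), with 11 of 15 at least 2-fold higher: the pseudokinase gene TRIB3 at 2.62, SLC7A11 at 2.60, CHAC1, which degrades glutathione, at 1.83 and DDIT3, which codes for CHOP, at 1.80. ATF4 itself was higher by 0.54 and DDIT4 lay at -0.08. Of 13 NRF2 targets, 7 were at least 2-fold higher, with a median of 1.20 (percentile 100.0), OSGIN1 at 2.69 and the heme oxygenase gene HMOX1 at 1.93. The antioxidant gene SRXN1 was not well above background in the control and at least 49.0-fold higher.

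The unfolded protein response genes had a median of 0.36 (percentile 99.99), with 15 of 16 above the control, none at 2-fold and HERPUD1 highest at 0.86. All 7 metallothioneins were above the control, with a median of 0.97 (percentile 100.0). Their differences with either drug alone use the same control array, so these values are not independent. With valproic acid added to bortezomib their median was 0.15 and not apart (percentile 90.55). The autophagy genes had a median of 0.45 (percentile 99.99), and 3 of 13 were at least 2-fold higher, WIPI1 at 1.12 beside GABARAPL1 and SQSTM1. Of 15 cholesterol genes, 13 lay below the control with a median of -0.45 (percentile 0.00), SQLE, an early enzyme of sterol synthesis, at -0.72 and INSIG1 at -0.63, whereas MVD lay at 0.37. The mitotic genes had a median of -0.38 (percentile 0.00), with 19 of 20 below the control and the proliferation marker MKI67 at -0.81. The B-cell precursor genes had a median of -0.22 (percentile 0.65), with 18 of 20 below the control, CD72 at -0.83 and VPREB3 at -0.75. Lists not apart were replication (-0.12), homologous recombination and checkpoint (-0.08), p53 targets (-0.16), NF-kappaB targets (0.00), pro-survival BCL2 genes (-0.03), pro-apoptotic BCL2 genes (-0.16), polyadenylated histones (0.04) and histone deacetylases (-0.12). BIK, higher with valproic acid, lay at -1.20 ± 0.24 with bortezomib.

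Outside the lists, DGKG, a diacylglycerol kinase gene, was higher by 4.30 ± 0.22, TNFRSF8, which codes for CD30, by 3.95 ± 0.28, the microtubule protein gene MAP1A by 3.81 ± 0.20 and PALM3 by 3.74 ± 0.20. RAI2 at 3.69 ± 0.33, GPNMB at 3.62 ± 0.22, NLRP12 at 3.61 ± 0.25, the exonuclease gene ISG20 at 3.40 ± 0.20, CALD1 at 3.39 ± 0.21 and ADCY7 at 3.25 ± 0.23 followed, and RAI2 was near its control level with both drugs (log2 signal relative to the 75th percentile of -5.53, against -5.97). The 1 spot of RAI2 lay just outside the definition of a patch, with 3 other bright spots within 3 rows and 3 columns on the bortezomib array, and its difference was 1.89 with normexp background correction. The T-cell surface gene CD2 was higher by 4.42 ± 0.26 on a spot that lay in a bright patch, and by 0.21 on its second probe. Not well above background in the control, TEX19 was at least 77.2-fold and the growth factor gene EGF at least 57.6-fold higher, while CAPZA3 (at least 163-fold) and CNBD1 (at least 68.1-fold) lay in bright patches of the bortezomib array. The 1 probe for 5.8S ribosomal RNA (RNA5-8SN5) was the lowest of the named genes measured on both arrays, at -2.41 ± 0.20, with FBLN5 at -2.01 ± 0.26, RPRML at -1.78 ± 0.21, PPFIA4 at -1.76 ± 0.23 and TIFAB at -1.70 ± 0.32 among those that followed. ELFN2, ISM1, MS4A4A, LFNG and GPR146 lay between -1.62 and -1.51, and LFNG lay at -0.33 on its second probe. NEFH at least 7.54-fold, TENT5C at least 5.41-fold and LCN8 at least 5.01-fold lower were not well above background with bortezomib, as were MIR1-1HG and RGL3 (at least 10.3-fold and 5.74-fold lower), bright in patches of the control array.

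The share of higher genes among the 2-fold differences was 73.3%, and with normexp background correction it was 82.8%, with 42 genes lower. The detection limit estimated from the spiked-in transcripts was out of the software's range on the bortezomib array (2.13, against 0.73 to 0.85 on the others). The values of its dimmest genes are therefore less certain, and no value was weighted for this.

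**Figure D2:**
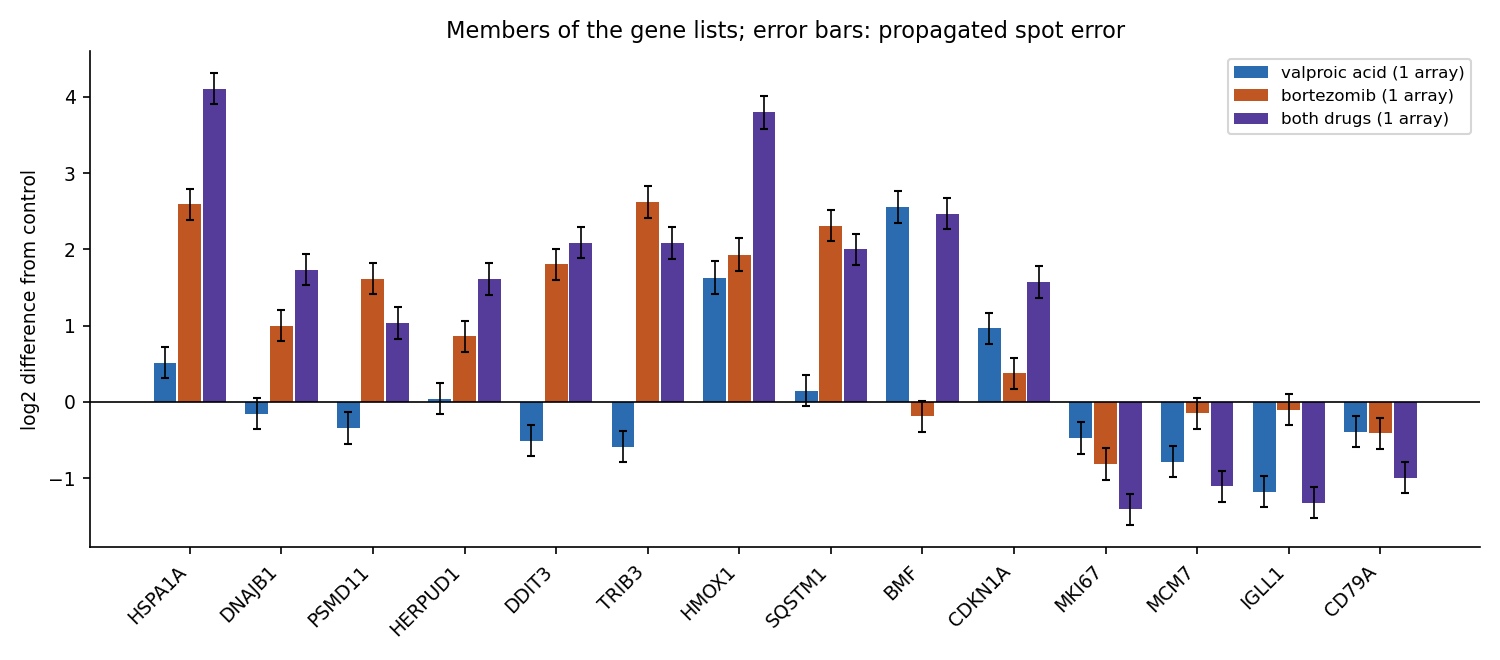
Log2 differences from the untreated control for 14 members of the gene lists, with valproic acid (blue), bortezomib (orange) and both drugs (purple), from 1 array each; error bars are the propagated spot error. HSPA1A stands at 0.51, 2.59 and 4.10, BMF at 2.56, -0.19 and 2.46, and MKI67 at -0.47, -0.81 and -1.41.

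The combination and control arrays were compared to ask what differed with both drugs together. With both drugs 1101 of 14087 measured genes were at least 2-fold higher and 562 at least 2-fold lower. The groups higher with bortezomib were higher here too, with HSPA1A at 4.10 ± 0.20 (17.2-fold; probe at hg19 positions 31785491 to 31785550 of chromosome 6), and so was the group of p53 targets, with CDKN1A at 1.57 ± 0.21. Mitotic, replication and B-cell precursor genes were lower, with medians below those of either drug. IL21R, a cytokine receptor gene, on chromosome 16 (hg19 positions 27461324 to 27461383), was the highest of the named genes measured on both arrays at 5.49 ± 0.27 (44.9-fold), and LAMP5 the lowest at -4.46 ± 0.26 (22.0-fold).

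All 20 mitotic genes lay below the control with a median of -0.86 (percentile 0.00), and 7 were at least 2-fold lower, led by MKI67 at -1.41, the ubiquitin ligase partner UBE2C at -1.26 and KIF20A at -1.25. Of 19 replication genes, 17 lay below the control with a median of -0.75 (percentile 0.00), E2F1 at -1.45 and MCM5 at -1.18. The homologous recombination and checkpoint genes had a median of -0.58 (percentile 0.15). All 20 measured B-cell precursor genes lay below the control with a median of -0.73 (percentile 0.00), and 5 were at least 2-fold lower: IGLL1 at -1.32, CD72 at -1.24, the transcription factors TCF3 at -1.23 and ERG at -1.12, and DNTT, the polymerase that diversifies antigen receptor joints, at -1.07. The pro-survival BCL2 genes had a median of -0.51, not apart (percentile 3.70), with BCL2 itself at -1.20. The pro-apoptotic genes had a median of 0.48 (percentile 99.6), with BMF at 2.46, BIK at 1.83 and BBC3 at 1.11.

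The ATF4-CHOP genes had a median of 1.52 (percentile 100.0) and 9 of 15 were at least 2-fold higher, SLC7A11 at 2.58, ATF3 at 2.18 and CHAC1 at 2.11. PHGDH, an enzyme of serine synthesis, lay below the control at -0.34. Heat shock genes had a median of 0.74 (percentile 100.0), all 19 above the control and 7 at least 2-fold higher, HSPA1B at 3.26 and DNAJB1 at 1.73. NRF2 targets had a median of 1.02 (percentile 100.0), with HMOX1 at 3.80. Proteasome genes had a median of 0.57 (percentile 100.0), with 31 of 35 above the control. Unfolded protein response genes had a median of 0.86 (percentile 100.0), with HERPUD1 at 1.61 and SDF2L1 at 1.32 among 4 at least 2-fold higher. Metallothioneins (1.15, percentile 100.0), p53 targets (0.56, percentile 99.99) and autophagy genes (0.39, percentile 99.1, WIPI1 at 4.54) were apart and higher. Of 16 p53 targets 5 were at least 2-fold higher and 2 at least 2-fold lower, TP53I3 at -1.62 and MDM2 at -1.27, and with the mean over members the list lay at 0.40 and was not apart. NF-kappaB targets had a median of 0.54 (percentile 99.9), with BIRC3 at 3.46 and RELB at 1.65. Cholesterol genes (-0.21), polyadenylated histones (0.02) and histone deacetylases (-0.05) were not apart.

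GABARAPL1 was higher by 5.42 ± 0.21, MIAT by 4.79 ± 0.21, SEL1L3 by 4.79 ± 0.31, PALM3 by 4.74 ± 0.20, the transcription factor gene KLF2 by 4.60 ± 0.28 and WIPI1 by 4.54 ± 0.22. TMEM130 and GRHL1 lay at 4.49 and 4.29. Next to LAMP5, the lowest named genes measured on both arrays were ELFN2 at -3.75 ± 0.21, the muscle creatine kinase gene CKM at -3.32 ± 0.20, TAFA1 at -2.98 ± 0.34 (-1.96 on its second probe), AOX2P at -2.75 ± 0.21 and H1-10-AS1 at -2.67 ± 0.22. GTF2IRD2, CACNG6, AVEN, HPDL, NCKAP5 and LRRC14B lay between -2.60 and -2.41. Not well above background in the control, TEX19 was at least 143-fold, SRXN1 at least 93.0-fold, MAPT, which codes for the tau protein, at least 56.8-fold, FBXO2 at least 54.3-fold and EGF at least 34.4-fold higher. ATP4B was at least 12.4-fold, DPEP1 at least 11.4-fold and EFEMP1 and LCN6 each at least 10.4-fold lower and not well above background with both drugs, as was MIR1-1HG (at least 11.6-fold), whose control spot lay in a bright patch.

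The share of higher genes among the 2-fold differences was 66.2%, and it was 51.5% with median centring and 77.9% with spike-in scaling. Among genes above the median of mean signal, the NF-kappaB median was 0.039 and the pro-apoptotic median 0.24, and neither was apart.

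**Figure D3:**
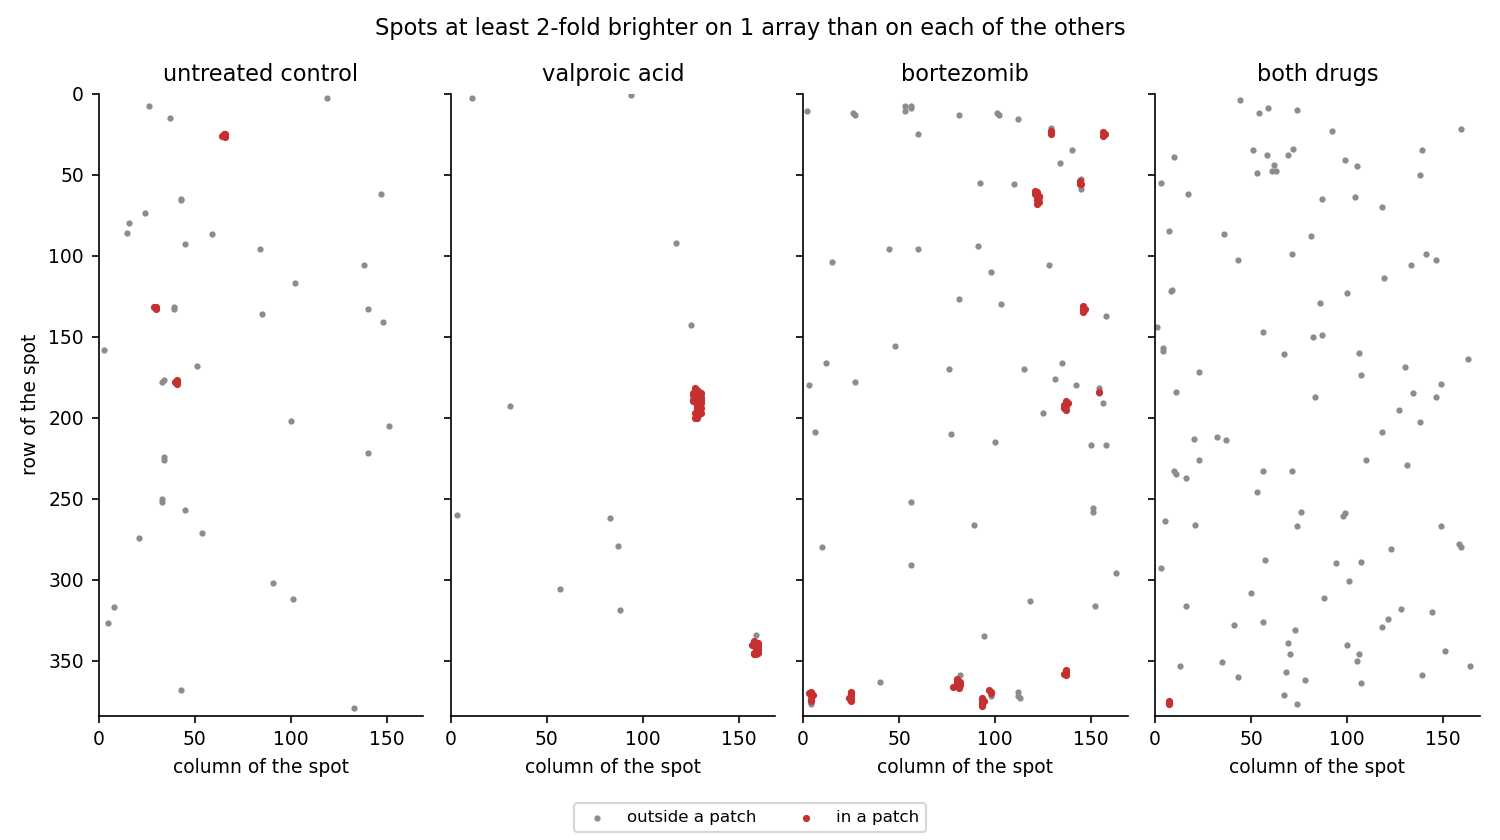
Column and row on each array of the 359 spots at least 2-fold brighter there than on all 3 other arrays, in red where at least 2 other such spots lie within 2 rows and 2 columns. Of these spots, 11 on the control array, 52 on the valproic acid array, 70 on the bortezomib array and 3 on the combination array lie in such patches.

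Markers of other blood cells were checked in the same way, to ask whether their genes differed between the treated arrays and the control. Other cells present in a like share on every array would cancel in these differences. The check therefore cannot tell whether the culture was mixed. T-cell markers had medians of -0.34, -0.08 and -0.36 with valproic acid, bortezomib and both drugs, and the first was apart (percentile 2.23). It was not apart with the mean over members (-0.23), normexp background correction (-0.21), the mean over probes (-0.19) or no filter on dim probes (-0.27), and with quantile normalization it was greater in size (-0.49) and just short of the limit (percentile 2.62). Myeloid markers had medians of 0.01, 0.11 and -0.01, although ITGAM lay at 1.48 with valproic acid and with both drugs and CSF1R at 1.26 with bortezomib. Erythroid and megakaryocyte markers had medians of -0.10, -0.06 and -0.21. Neither of these lists was apart against the control.

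The combination and bortezomib arrays were compared to ask how valproic acid acted when bortezomib was present, and the combination and valproic acid arrays to ask the same of bortezomib. With bortezomib present, valproic acid went with MAPT higher by 4.58 ± 0.35, the G protein gene GNAZ by 4.26 ± 0.21, the adhesion gene MCAM by 4.18 ± 0.22, KLF2 by 4.16 ± 0.25 and MTURN by 4.08 ± 0.26. LAMP5 at -3.42 ± 0.26, the aminotransferase gene GPT2 at -2.78 ± 0.21, CKM at -2.50 ± 0.20 and AOX2P at -2.45 ± 0.21 were lower, and so were RAI2, with other bright spots near its own, at -3.25 ± 0.27 and CD2, bright in a patch of the bortezomib array, at -4.78 ± 0.27. With valproic acid present, bortezomib went with higher SRXN1 (5.18 ± 0.28), TEX19 (4.45 ± 0.21), RGS16, a brake on G protein signalling (4.18 ± 0.21), EGF (4.09 ± 0.31), PALM3 (3.66 ± 0.20) and HSPA1A (3.59 ± 0.20). RNA5-8SN5 at -2.01 ± 0.20, FBLN5 at -1.82 ± 0.21 and SPOCD1 at -1.90 ± 0.34 were lower, as were LINC00994, SLC25A41 and TCF23 (-5.00, -4.23 and -2.40), bright in patches of the valproic acid array.

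Counts were 956 higher and 262 lower of 14140 for valproic acid added to bortezomib, and 268 higher and 138 lower of 14498 for bortezomib added to valproic acid, or 600 and 158, and 177 and 44, with normexp background correction. The higher shares of 78.5% and 66.0% were 68.1% and 73.1% with median centring, and the first was 86.4% with spike-in scaling and the latter 80.1% with normexp background correction. Replication genes (-0.62, percentile 0.00), mitotic genes (-0.55, percentile 0.00), homologous recombination genes (-0.52, percentile 0.04), B-cell precursor genes (-0.44, percentile 0.02) and pro-survival BCL2 genes (-0.59, percentile 0.77) were lower with valproic acid added to bortezomib. Proteasome genes were lower too: all 35 lay below the bortezomib array, with a median of -0.37 (percentile 0.01). Unfolded protein response genes (0.49), p53 targets (0.57), NF-kappaB targets (0.53), pro-apoptotic genes (0.41), cholesterol genes (0.21) and heat shock genes (0.12) were apart and higher. ATF4-CHOP genes (-0.02, percentile 76.0) and metallothioneins (0.15, percentile 90.55) were not apart. Among genes above the median of mean signal, NF-kappaB targets (0.070), pro-apoptotic genes (-0.020) and pro-survival genes (-0.41) were not apart, nor were cholesterol genes with the mean over members (0.22). With bortezomib added to valproic acid, ATF4-CHOP genes (1.69), NRF2 targets (1.19), heat shock genes (0.92), proteasome genes (0.72), unfolded protein response genes (0.50), autophagy genes (0.38), NF-kappaB targets (0.37) and metallothioneins (0.30, but 0.27 and not apart with normexp background correction) were apart and higher. Mitotic (-0.51), B-cell precursor (-0.43), replication (-0.32) and cholesterol genes (-0.22, but -0.17 and not apart with the mean over members) were apart and lower. Not well above background on the valproic acid array, FFAR3 was at least 15.0-fold, STYK1 at least 11.8-fold and FAM81B at least 9.81-fold higher with both drugs, next to LINC00606 and TRIM53AP, bright in a patch of the combination array (at least 41.9-fold and 11.8-fold). Not well above background on the bortezomib array, FBXO2 was at least 48.4-fold, CCND2 at least 39.3-fold, TPD52L1 at least 30.8-fold and TRIM7 at least 30.7-fold higher with both drugs, and LINC00606 at least 30.3-fold. All 5 genes named as not well above background with both drugs against valproic acid alone (ARHGAP20, OR8U8, CBLN1, LINC02593 and SSMEM1) and all 5 named against bortezomib alone (CAPZA3, CNBD1, CNTN5, BAIAP2L1 and TAC3) lay in bright patches.

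**Figure D4:**
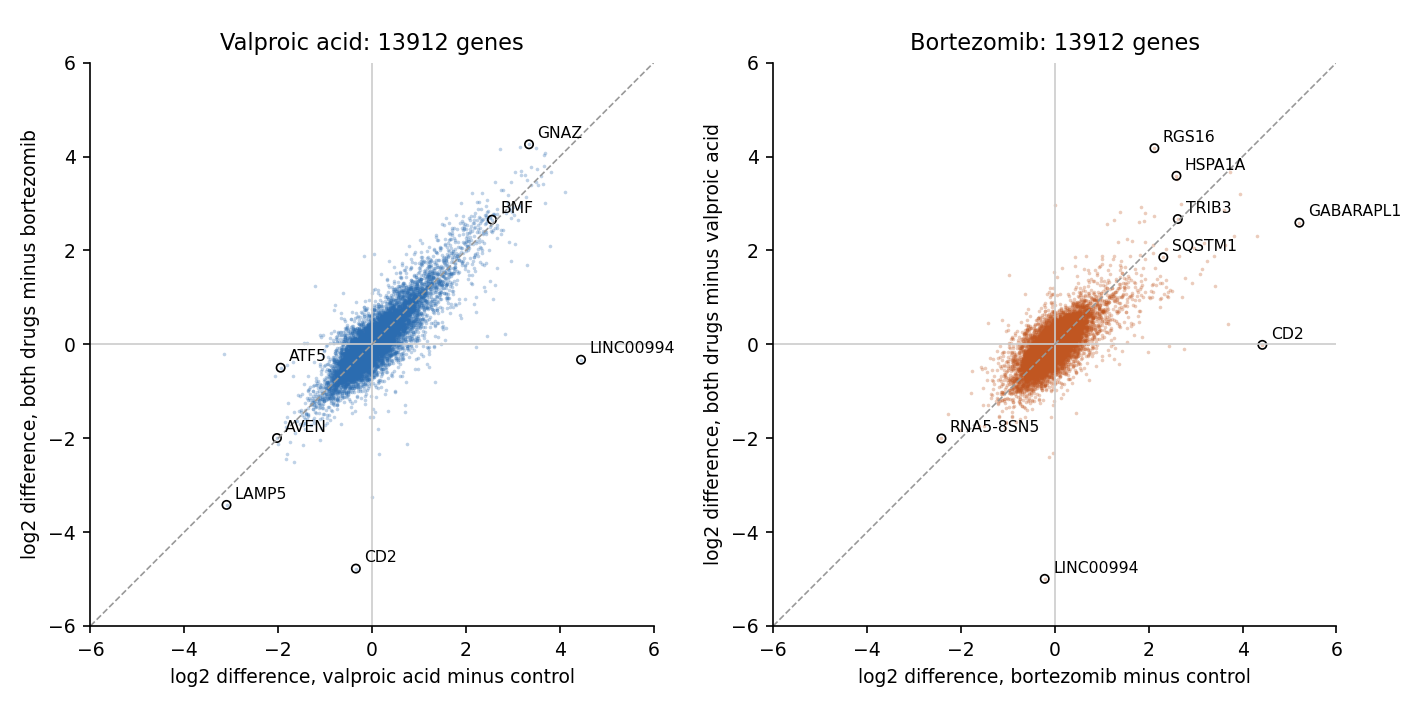
For each of 13912 genes measured on all 4 arrays, the left panel sets the valproic acid difference without bortezomib (horizontal, log2) against that with bortezomib (vertical, log2), the right panel does so for bortezomib, and the dashed line marks equal values. Pearson's r across genes was 0.867 on the left and 0.729 on the right, and LINC00994 and CD2, far from the line, lay in bright patches.

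The difference without the other drug and the difference with it share no array, so their correlation across the 13912 genes compares separate pairs of arrays, although genes are not independent replicates. For valproic acid Pearson's r was 0.867 and Spearman's rho 0.798, and for bortezomib 0.729 and 0.694. Without the filter on dim probes Pearson's r was 0.673 for valproic acid and 0.430 for bortezomib. Of 845 genes at least 2-fold higher with valproic acid alone, 662 were so with bortezomib present (55.7 would overlap if the lists were independent), as were 119 of 168 lower genes (3.1). For bortezomib these were 158 of 296 higher (4.94) and 41 of 103 lower genes (0.911). The differences of the 2 drugs from the control share the control array: r was 0.110 and rho 0.109. The 0.501 simulated with no effect follows from sharing that array, whatever the noise, so it is no yardstick for differences that hold drug effects. The covariance of the 2 differences was 0.0268. Simulated values were 0.0101 with the spread of replicate spots and 0.0236 with an upper bound on the noise. At least 2-fold, 75 genes were higher with both (18 for independent lists) and 8 lower with both (1.24). The simulations gave 0 for either overlap, but their noise was too small for a gene with no effect to reach 2-fold. They do not tell how much the shared control adds to these overlaps. Overlaps in opposite directions were also above those of independent lists: 27 genes were higher with valproic acid and lower with bortezomib (6.26), and 7 the other way (3.57). Of the 845 genes higher with valproic acid, 45.6% lay above the control with bortezomib, and of the 168 lower genes 70.2% lay below it. The shared control can add to overlaps in the same direction.

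The combination was also compared with the sum of the differences of the single drugs, to ask whether the drugs acted other than additively on the log2 scale. Of 13912 genes, 52 lay at least 2-fold above the sum and 86 below it, or 16 and 31 with normexp background correction. The heat shock genes lay above it, with a median of 0.38 (percentile 100.0) and HSPA1A at 1.00 ± 0.29, and so did the ATF4-CHOP genes, with a median of 0.32 (percentile 100.0), ATF5 at 1.45 ± 0.29 and CHAC1 at 1.10 ± 0.29. Metallothioneins (-0.67), autophagy genes (-0.17, but -0.11 and not apart with normexp background correction), B-cell precursor genes (-0.19), proteasome genes (-0.16) and mitotic genes (-0.15) lay below it. RIT1, a small GTPase gene, was the named gene farthest above the sum, at 2.46 ± 0.30 (-1.22 with valproic acid alone and 1.24 with valproic acid added to bortezomib), followed by RGS16 at 2.06 ± 0.29 and 1.98 on its second probe, the vasoactive peptide gene ADM at 1.87 ± 0.29, and RASSF8 at 1.70 ± 0.42.

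GABARAPL1, higher with each drug, lay below the sum at -2.62 ± 0.29. RAI2, with other bright spots near its own, lay at -3.26 ± 0.47, and LINC00994 (-4.78), CD2 (-4.43), ANGEL1 (-2.47) and TCF23 (-2.28) lay in bright patches. Unfolded protein response (0.18), NF-kappaB (0.28), pro-apoptotic (0.15) and cholesterol genes (0.20) were apart above the sum, and replication (-0.09, percentile 2.19), pro-survival BCL2 (-0.29) and myeloid genes (-0.47) below it. Not apart were replication genes with quantile normalization (-0.093), pro-survival and myeloid genes with the mean over members (-0.22 and -0.27), and pro-survival and pro-apoptotic genes among genes above the median of mean signal (-0.16 and 0.16). With the mean over probes, pro-apoptotic (0.13) and autophagy genes (-0.12) were not apart. Second probes matched less well here than in the other comparisons (r of 0.391 over 3450 genes, against 0.687 to 0.776), and the share above the sum was 37.7%, or 51.4% with median centring.

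A limma fit over the 4 arrays estimated an additive effect of each drug, and genes with Benjamini-Hochberg adjusted p under 0.05 were counted. The words rose, raised and fell below mean passing this threshold on these arrays. With 1 culture per group the p-values do not measure the spread between cultures. The fit assumes additivity and does not test it. It leaves 1 residual degree of freedom and takes any departure from additivity as error. With valproic acid 2540 of 13912 genes rose and 2311 fell, and with bortezomib 1040 rose and 1150 fell. The split with valproic acid depends on the scaling: it was 2137 and 4702 with median centring and 3332 and 1297 with spike-in scaling. Bortezomib raised 30 of 35 proteasome genes (33 adjusted over the list alone), 14 of 19 heat shock genes (17 adjusted over the list alone), 13 of 15 ATF4-CHOP genes (14 adjusted over the list alone) and 9 of 13 NRF2 targets (10 adjusted over the list alone). Of 16 unfolded protein response genes, 8 rose with bortezomib (11 adjusted over the list alone), and 8 rose and 1 fell with valproic acid (8 and 1 adjusted over the list alone). Of 7 metallothioneins 0 passed with either drug (4 with valproic acid and 6 with bortezomib at an unadjusted p under 0.05, and 0 and 6 adjusted over the list alone). Of 13 autophagy genes 6 rose with bortezomib (7 adjusted over the list alone). With valproic acid 13 of 19 replication genes (18 adjusted over the list alone), 8 of 11 homologous recombination genes (9 adjusted over the list alone), 11 of 20 mitotic genes (14 adjusted over the list alone) and 12 of 35 proteasome genes (9 adjusted over the list alone) fell. Of the p53 targets 9 of 15 rose with valproic acid and 2 fell (10 and 2 adjusted over the list alone). Of the B-cell precursor genes 8 of 20 fell and 1 rose with valproic acid, and 6 fell with bortezomib (12 and 10 fell adjusted over the list alone). Of 20 mitotic genes 10 fell with bortezomib (16 adjusted over the list alone), and of 15 cholesterol genes 4 fell (8 adjusted over the list alone). Among single genes, the fitted effect was 2.61 for BMF with valproic acid, and 2.64 for TRIB3 and 3.09 for HSPA1A with bortezomib. HSPA1A nevertheless lay above the sum of the single drugs. Without the filter on dim probes the fit called 1334 genes for valproic acid and 0 for bortezomib, where 4071 had an unadjusted p under 0.05.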

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

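Both searches of this part were set before the data were examined. The check of RIT1 for bright patches used a definition chosen after seeing the data, and no other test was chosen after a result was seen. RIT1, a small GTPase gene, lay at -1.22 ± 0.21 with valproic acid alone and at 1.24 with valproic acid added to bortezomib, and it is listed here because these directions are opposite. The difference between them was not tested, since each rests on 1 array per group. RIT1 has 1 measured probe, on chromosome 1 (hg19 positions 155867667 to 155867726). The check for bright patches marks only spots at least 2-fold brighter on 1 array than on all 3 others. The log2 signal of RIT1 was -2.59 in the control and -2.33 with both drugs. The check could therefore not mark RIT1, and it does not tell whether a patch affected its spots.

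The 8263 unnamed probes on loci of long intergenic non-coding RNAs, which no comparison above used, are listed because they also held signals above the control. With valproic acid 75 of 4560 measured probes were at least 2-fold higher and 38 lower. With bortezomib 75 of 4470 were higher and 19 lower, and with both drugs 99 of 4458 were higher and 115 lower. In the same order the higher shares were 1.6%, 1.7% and 2.2%, against 6.3%, 2.1% and 7.8% of the measured named genes. The lower shares were 0.83%, 0.43% and 2.6%, against 1.3%, 0.77% and 4.0%. How far bright patches enter these counts of probes was not examined.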

How the results depend on the processing

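Scaling on the spiked-in transcripts and leaving out bright patches were chosen only after the results were seen, and the other alternatives before. No paired analysis was possible because each group had 1 array, and leaving out replicates was not applicable for the same reason. Over all alternatives, 24 of 27 correlations moved by less than 0.1, 100 of 164 counts stayed within 1.5 times their first value, 1477 of 1536 list medians kept their direction and their side of the limits, and 1748 of 1905 values of single genes moved by less than their spot error, with 0 reversed. These totals include outcomes fixed in advance. Median centring, the authors' value table and spike-in scaling shift all genes of an array alike. Correlations and list percentiles, 3 and 156 for each of these settings, could therefore not change. Values of single genes were fixed in the same way, because the shifts were smaller than the spot error. With valproic acid the median of all genes moved from -0.05 to -0.23 with median centring and to 0.09 with spike-in scaling. In each of these settings 274 of 274 values of single genes stayed within their error, which is no sign of robustness. The single genes were picked for large differences, which makes a reversal less likely. Of the 157 values of single genes that moved by more, 132 did so with normexp, where 132 of 274 values moved, all 132 of them towards 0, so the size of many named differences depends on the background correction. Another 12 values of single genes are not in these numbers, since no spot was left for them once bright patches were left out. Of 1536 list medians 30 were no longer apart, 26 became apart and 3 that had been apart changed sign. With a difference above 2 times its error, all 12 counts stayed within 1.5 times. The median error was 0.20 for 2 arrays and 0.29 for the sum, so most log2 differences of at least 1 met this condition already. Signal over background limits the dim genes most, and among genes above the median of mean signal some lists had too few members to give a value. Where no reason is given below, the cause was not tested.

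Counts follow in the order higher, lower for valproic acid, bortezomib, both drugs (each against the control), both drugs against valproic acid and both drugs against bortezomib, then above and below the sum of the single drugs. A threshold of 1.5-fold, which counts more genes by construction, gave 1858, 993, 784, 769, 2258, 1892, 864, 919, 1841, 1236, 370 and 433. A threshold of 3-fold, which counts fewer, gave 358, 25, 104, 7, 457, 89, 74, 13, 387, 35, 6 and 17. No filter on dim probes, which tests more genes, gave 1533, 618, 721, 473, 1784, 976, 698, 527, 1565, 634, 719 and 715. Genes above the median of mean signal, which are fewer, gave 137, 61, 127, 18, 262, 272, 107, 29, 167, 95, 5 and 15. Normexp background correction gave 507 higher and 114 lower with valproic acid, 42 lower with bortezomib, 177 higher and 44 lower with both drugs against valproic acid, 600 higher and 158 lower with both against bortezomib, and 16 above and 31 below the sum. Genes lower with valproic acid numbered 348 with median centring, 348 with the authors' value table and 114 with spike-in scaling.

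The correlation of a drug's difference without and with the other was 0.673 for valproic acid and 0.430 for bortezomib with no filter, and 0.840 for bortezomib among genes above the median of mean signal. The additive limma fit called 1334 genes for valproic acid and 0 for bortezomib with no filter (6111 and 4071 at an unadjusted p under 0.05), and for bortezomib 3976 with normexp and 3927 with a trended prior variance.

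Among genes above the median of mean signal, medians that changed sign were those of the pro-apoptotic genes with valproic acid (-0.18) and with valproic acid added to bortezomib (-0.020) and of the immediate early genes with both drugs (-0.21). No longer apart there were NF-kappaB targets with both drugs (0.039) and with valproic acid added to bortezomib (0.070), pro-survival genes with valproic acid added (-0.41) and against the sum (-0.16), pro-apoptotic genes with both drugs (0.24) and against the sum (0.16), ribosomal genes against the sum (0.10), interferon genes with valproic acid (0.028) and immediate early genes with bortezomib added (0.012). Interferon genes with bortezomib added (0.50) and hypoxia genes with both drugs (-0.55) became apart.

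With the mean over members, medians no longer apart were metallothioneins with bortezomib added (0.28), p53 targets with both drugs (0.40), pro-survival genes against the sum (-0.22), cholesterol genes with bortezomib added (-0.17) and with valproic acid added (0.22), hypoxia genes with valproic acid (-0.12), T-cell markers with valproic acid (-0.23) and myeloid markers against the sum (-0.27). Those that became apart were NF-kappaB targets with valproic acid (0.43), pro-survival genes with both drugs (-0.59) and with bortezomib added (-0.33), B-cell precursor genes with valproic acid (-0.27), autophagy genes with valproic acid (0.46), interferon genes with bortezomib added (0.21), hypoxia genes with valproic acid added (0.27), immediate early genes with valproic acid added (0.72) and against the sum (0.27), and T-cell markers with bortezomib (0.53), with valproic acid added (-0.90) and against the sum (-0.67), where CD2 lay in a bright patch.

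Normexp left metallothioneins with bortezomib added (0.27), autophagy genes against the sum (-0.11), ribosomal genes against the sum (0.089) and T-cell markers with valproic acid (-0.21) no longer apart, and immediate early genes with valproic acid added (0.24) became apart. Quantile normalization left replication genes (-0.093) and ribosomal genes (0.013) against the sum and T-cell markers with valproic acid (-0.49) no longer apart, while p53 targets against the sum (0.14), pro-survival genes with both drugs (-0.58), B-cell precursor genes with valproic acid (-0.17) and immediate early genes with valproic acid added (0.43) and against the sum (0.19) became apart. The mean over probes left pro-apoptotic genes with valproic acid (0.23) and against the sum (0.13), autophagy genes against the sum (-0.12) and hypoxia genes (-0.26) and T-cell markers (-0.19) with valproic acid no longer apart, while p53 targets against the sum (0.15), B-cell precursor genes with valproic acid (-0.27), immediate early genes with valproic acid added (0.27) and T-cell markers with both drugs (-0.50) became apart. With no filter, p53 targets against the sum (0.14) became apart and T-cell markers with valproic acid (-0.27) no longer were, and with bright patches left out p53 targets against the sum (0.15) became apart.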

Other observations

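For the patterns weighed here, all tests except that of the other probes of the ATF4-CHOP and heat shock genes were chosen only after the result was seen. Interferon-stimulated genes were higher as a group against the control with each drug: the median was 0.49 with valproic acid (percentile 99.95), 0.22 with bortezomib (percentile 99.5) and 0.69 with both (percentile 99.97), over 17 genes of which 5, 6 and 6 were at least 2-fold higher. These medians share the control array and are not independent. With bortezomib added to valproic acid the list was not apart, but it became apart with the mean over members (0.21) and among genes above the median of mean signal (0.50). IFI44L, a gene of the antiviral response, lay between 2.37 and 3.72, and OAS1, which senses double-stranded RNA, at 2.21, 1.55 and 2.56. ISG15 lay at -0.21, -0.66 and -0.83. The list lay below the sum of the single drugs, with a median of -0.28 (percentile 0.02), and the valproic acid median was 0.028 and not apart among genes above the median of mean signal. In the limma fit 8 of 17 rose with valproic acid and 5 with bortezomib (8 and 7 adjusted over the list alone), while 1 fell with valproic acid and 2 with bortezomib (2 and 3 adjusted over the list alone).

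Hypoxia and glycolysis genes were lower with bortezomib, with a median of -0.54 (percentile 0.00) and 11 of 14 below the control, LDHA, which makes lactate, at -0.71, HK2 at -0.81 and the peptide gene ADM at -1.42. With valproic acid the median was -0.37 (percentile 0.19), with NDRG1 at 1.99 against it. The mean over members (-0.12) and the mean over probes (-0.26) were not apart. With both drugs the median was -0.12 and not apart, with ADM at 0.50, and the list lay above the sum by 0.38 (percentile 100.0). Among genes above the median of mean signal, however, the list with both drugs lay at -0.55 and was apart (percentile 1.06). Against the control, immediate early genes were apart with both drugs, at a median of 0.54 (percentile 99.6), but not with valproic acid (0.09) or bortezomib (-0.09) alone. With both drugs JUN lay at 3.58, FOS at 1.58 and EGR1 at 1.35, and the median was 0.47 when bortezomib was added to valproic acid. Among genes above the median of mean signal the median was -0.21 with both drugs and 0.012 with bortezomib added, and neither was apart. When valproic acid was added to bortezomib (0.24) and against the sum of the single drugs (0.14) the list was not apart, but it became apart with quantile normalization (0.43 and 0.19) and with the mean over members (0.72 and 0.27), and the first also with normexp background correction (0.24) and with the mean over probes (0.27). Neuronal genes had medians of 0.11, 0.02 and 0.05 with valproic acid, bortezomib and both drugs, with the vesicle protein gene SYT1 at 1.21, -0.89 and 1.18. Ribosomal protein genes had medians of -0.12, -0.03 and -0.07, none of them apart.

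The first pattern is the set of genes bright on 1 array, since it decides which single genes can be followed up. Of 359 spots at least 2-fold brighter on 1 array than on the others, 136 lay in patches, against 1 with positions shuffled, and for 1 of 48 testable spots in patches the other spots of the probe were higher too, which argues against a response of the gene there. For 124 of 145 testable spots outside patches the other spots of the probe were higher too, which argues against marks on the array for these. Genes such as KLF2, HMOX1, HSPA1A, PCP4 and NLRP12 each hold many of the bright spots outside patches, so the spots are not independent evidence. Bright spots whose probe has 1 spot could not be tested. A candidate explanation for the patches is a mark on the array surface, and 14 of the 34 genes named by a bound lay in one, along with CD2, LINC00994, SLC25A41, TCF23 and ANGEL1.

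The second pattern is the ATF4-CHOP genes at 0.32 and the heat shock genes at 0.38 above the sum of the single drugs. With quantile normalization and with normexp background correction the percentile of either list stayed at 100.0, which argues against these processing choices as the whole explanation. Median centring, the authors' value table and spike-in scaling shift all genes of an array alike. They could not change a percentile, so they do not bear on this. An error of single probes is argued against by the 14 other measured probes of 11 of these genes, with a median of 0.42. What stays open is that 1 of the 4 arrays stood off for these genes: the ATF4-CHOP median with valproic acid was -0.59 without bortezomib and -0.02 with it, and with 1 array per group this cannot be told apart from an effect of the drugs together. Replicate arrays would be needed to decide between these.

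The third pattern is the probe of 5.8S ribosomal RNA (RNA5-8SN5), at a log2 signal of 6.36 in the control and 6.23 with valproic acid, against 3.94 with bortezomib and 4.22 with both drugs. A mark on the surface is argued against by 13 neighbouring spots, with medians of 0.088 (bortezomib minus control) and 0.063 (both drugs minus valproic acid). Less ribosomal RNA in the labelling is argued against by 5 probes of 28S and 18S ribosomal RNA, with medians of 0.019 and 0.096. The pattern rests on 1 probe with 1 spot per array, and a lower level of this RNA with bortezomib may be followed up with another method, as a hypothesis.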
